A study of Hordeum vulgare with 18 samples.

How the data were processed

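Barley seedlings were grown for 4 days on wet filter paper and transferred, as germinated seeds, to dishes with methyl jasmonate for 3, 6 or 24 h, per the labels' protocols. Shoot and root RNA came from 3 germinated seeds per sample, and 400 ng of total RNA was labelled, per the labels. The 18 arrays are 2-colour Agilent arrays with 60-base probes. On every array the labels give Cy3 to untreated 0 h RNA and Cy5 to treated RNA of the same organ, so all ratios run one way and no dye was swapped.

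The authors deposited 1 scanner table per array. Its spot brightness in both channels is an intensity on a linear scale, per the file headers, with the local background beside it. Its log ratio is a log10 value of red over green processed signal, per the file headers, and the files bear this out to within 4.17e-07. The submitters' processing notes name Agilent Feature Extraction 9.1; the file headers give a 9.1 release on 2 arrays, those of replicate 1 at 6 h, and a later release on the other 16. The deposited value table of the series holds the same log10 ratios with a largest difference of 0, so its scale and direction are settled; its array medians lay between -0.00817 and 0.

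From the intensity columns, backgrounds were corrected with normexp (offset 50) and ratios were normalised by loess within each array in limma 3.58.1 under R 4.3.3. Control spots had no weight in the loess, and 948 values marked as outliers by the scanner software were left out. Each array holds 42483 probes of 36632 clones on 1 spot each. Probes well above background in either channel on at least 4 of the 16 replicated arrays were kept, which dropped 3066. A mean per group was fitted over the 16 arrays of the 4 replicated groups. All groups share an estimate of the spread with 12 residual degrees of freedom. Empirical Bayes moderation and Benjamini-Hochberg adjustment over the probes of a comparison followed. Same-numbered arrays deviated together, so 12 overstates the independent information on the spread, and adjusted p values may be too small. Untreated shoot and root were compared on the Cy3 log2 intensities after loess and Aquantile normalisation, averaged per organ and replicate number. The 24 h arrays entered no fit of ratios, but their Cy3 channels were among those averaged for replicate 1 in the untreated comparison. The bound of a fold sets the brighter mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal, per channel after loess and Aquantile; with 2 dyes it stays open to dye bias.

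The replicate numbers of the labels were checked for pairing. Deviations of same-numbered arrays from their group means correlated at 0.54 to 0.79 across probes between 3 h and 6 h of an organ, and at 0.15 to 0.38 between shoot and root at the same time, with 1 pair across organs and times as low as 0.067. The numbers therefore pair the samples. Cy3 channels of the same organ and number differed by a median absolute deviation of 0.05 to 0.13 in log2, against 0.19 to 0.53 between numbers, so arrays of a number carry the same, or nearly the same, 0 h RNA. Cy5 deviations of same-numbered arrays correlated as well, at 0.33 to 0.68. Replicates 2, 3 and 4 each lie on a slide of their own with all 4 groups, and replicate 1 is spread over 2 slides and was scanned in an earlier batch. A slide or the earlier batch holds at most 1 array per group among those fitted, so no test within it is possible; the later batch alone is the fit without replicate 1.

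Choices made before the data were examined were the tests, the filter, the call and the alternatives of background correction, normalisation, filter, fold minimum, fit and pairing. Chosen after seeing the data were a replicate block within each tissue, 1 probe per clone, leaving out the slide 1 arrays, and slide as a block. The probe sets followed to 24 h were first taken from calls that included replicate 1, the replicate of the 24 h arrays; after these values had been seen, they were replaced by sets called from replicates 2 to 4 alone, since selection favoured replicate 1 at 3 h and 6 h. Chance overlaps of calls were simulated by turning the scaled deviations of same-numbered arrays by each of the 16 sign patterns of the 4 numbers. These deviations come from ratios of treated tissue against 0 h, so they also hold differences between replicates in the size of a response. A constant dye effect of a probe is removed with the group means. The simulations therefore lack the shared calls and covariance that dye alone could give. Covariances were averaged over all 16, and shared calls over the 14 that do not force every mean to 0. This replaced, after its result had been seen, a random draw from the same patterns that had kept the other 2 in the counts. The fits were tested on simulated data with 200 changed probes per group among 39417. Noise was drawn independently for each array, unlike that of the paired arrays. With fewer true changes the adjusted threshold is stricter than in these simulations. The shares recovered therefore do not give the chance of a call between 6 h and 3 h on the real arrays. Changes of 1.5 on the log2 scale were recovered in 95.5% of cases for shoot at 3 h, in 88.1% for root at 6 h, in 87.1% for 6 h against 3 h in shoot, in 84.3% for shoot minus root at 6 h and in 73.1% for untreated shoot minus root.

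The rule for named items asked for annotated genes. No probe had a descriptive gene name, and 0 probe or clone IDs occur among the 58438 genes of the reference table (assembly MorexV3). The 2 highest and 2 lowest clones per comparison are named instead, under the rule's other conditions: called, same sign on all 4 arrays and well above background in the brighter channel on all 4, or, for differences, called with non-overlapping arrays. A clone is represented by its probe of highest mean intensity. Tests of 34 gene lists fixed beforehand, including markers of shoot, root and seed, were not run, as no list could be matched to probes. Clones with 2 probes numbered 5747, and 96.3% of these pairs share at least 20 bases; their mean log2 ratios correlated at 0.99 across clones in shoot at 3 h. Probe sequences were compared with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9.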

Results

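The series followed messenger RNA in seedlings of barley (Hordeum vulgare, cultivar Haruna Nijo) after transfer to methyl jasmonate, the volatile ester of the plant stress hormone jasmonic acid. Shoots and roots were harvested separately, and each 2-colour array set RNA of treated tissue, labelled with Cy5, against RNA of the same tissue taken at 0 h without treatment, labelled with Cy3. A positive log2 ratio therefore means a higher level in the treated tissue. There were 4 arrays each for shoot at 3 h, shoot at 6 h, root at 3 h and root at 6 h, and 1 array each for shoot and root at 24 h. The labels call the replicates biological and give the dose as 100 mM, a unit that the files cannot check. Between 86.8% and 90.7% of the 42483 probes lay well above background in Cy5, and 39417 probes were tested. The median Cy3 signal ranged from 670 to 1225 and the median Cy5 signal from 1055 to 2298. The number of arrays limits the precision of every mean. The files do not pair probes with genes, so probes are named by their clone ID. A probe is called here when limma's adjusted p was under 0.05 and its mean log2 ratio, or difference, was at least 1 in size. No dye was swapped and no mock-treated seedlings of the same age were on the arrays, so a ratio against 0 h also holds any dye effect of the probe and any change due to the transfer and the hours that followed.

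The Cy3 channels gave the starting levels of both organs, which differed widely. Of the probes tested, 7097 were at least 2-fold higher in untreated shoot and 8443 at least 2-fold higher in untreated root, with 4 samples per organ. The median log2 difference of shoot minus root over all probes was -0.352, and these counts were not centred on it. Probe Hv2031M03_1 (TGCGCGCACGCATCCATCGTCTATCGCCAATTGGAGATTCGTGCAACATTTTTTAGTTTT) had a log2 intensity of 16.54 ± 0.37 in shoot and 6.24 ± 0.29 in root (SD, n = 4), with an adjusted p of 1.36e-09. Probe Hv1027M07_1 stood at 16.86 ± 0.25 in shoot and 6.69 ± 0.65 in root. Both lay well above background on only 2 of the 9 root arrays, so their folds of 1270 and 1150 rest partly on root signals near background. In the other direction, Hv2117E22_1 (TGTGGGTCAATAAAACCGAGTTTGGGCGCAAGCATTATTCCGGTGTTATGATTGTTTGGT) stood at 6.08 ± 0.14 in shoot, a difference of shoot minus root of -9.92 with an adjusted p of 3.27e-10, and was well above background on 1 of the 9 shoot arrays. Probe Hv2064J08_1 was not well above background on any shoot array and was at least 959-fold higher in root. At 4-fold or more the order turned, with 4534 probes higher in shoot and 2942 in root.

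In shoots after 3 h of treatment, transcripts that rose outnumbered those that fell. There were 1365 probes called higher and 307 called lower than at 0 h, so that 81.6% of the called probes had risen. The largest mean increases were those of Hv1054H21_1 (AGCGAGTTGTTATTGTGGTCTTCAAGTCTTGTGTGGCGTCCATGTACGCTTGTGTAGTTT) and Hv2083E12_1 (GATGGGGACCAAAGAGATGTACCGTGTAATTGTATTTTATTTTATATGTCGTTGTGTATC). Hv1054H21_1 had a mean log2 ratio of 6.71 ± 2.29 (SD, n = 4), a 104-fold increase, with an adjusted p of 0.000249. Its replicates ranged from 4.01 to 9.45. Hv2083E12_1 had a mean of 6.61 ± 2.76, and its replicates ranged from 3.68 to 10.17. Without replicate 1 the means were 5.79 for Hv1054H21_1 and 5.43 for Hv2083E12_1, and without replicate 3 they were 7.60 and 7.59. Decreases were smaller. Hv2104L08_1 (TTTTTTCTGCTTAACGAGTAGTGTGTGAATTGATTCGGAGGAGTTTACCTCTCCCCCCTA) had a mean of -2.80 ± 0.48 and an adjusted p of 2.43e-06, and Hv1128K05_1 a mean of -2.49 ± 0.57. At 4-fold or more, 348 probes were higher and 9 lower, and at 8-fold or more, 86 were higher and 0 lower. For 5 of the called increases the 0 h channel was never well above background, so their fold is a bound. With the scanner software's own processed signals in place of the loess-normalised ratios, 1793 probes were called higher and 758 lower, which lowers the rising share to 70.3%.

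**Figure D1:**
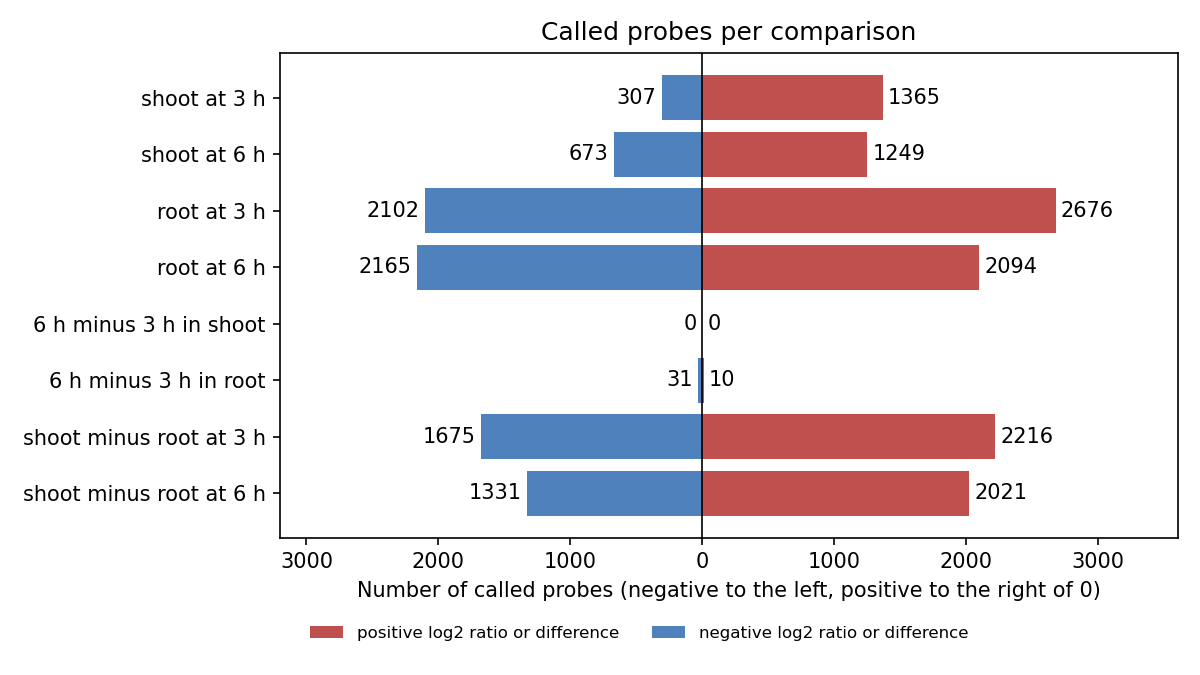
Number of called probes in each comparison (horizontal axis, probes with a positive mean to the right of 0 and with a negative mean to the left). The 4 upper bars are treated tissue against 0 h and the others are differences between times or organs; root had more called probes than shoot at both times, and no probe was called between 6 h and 3 h in shoot.

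At 6 h the shoot showed 1249 probes called higher and 673 called lower than at 0 h, or 1726 and 1216 with the scanner software's processed signals. Hv2083E12_1 had the highest mean log2 ratio, 7.76 ± 1.78 (SD, n = 4), a 217-fold increase with an adjusted p of 0.000347. Hv1054H21_1 followed with 7.40 ± 0.77, and its replicates lay between 6.70 and 8.33. The replicates of Hv2083E12_1 ranged from 6.34 to 10.18, and without replicate 1 its mean was 6.95, below the 7.09 of Hv1054H21_1. Hv2104L08_1 again had the lowest mean, -2.81 ± 0.17, and Hv2106H03_1 (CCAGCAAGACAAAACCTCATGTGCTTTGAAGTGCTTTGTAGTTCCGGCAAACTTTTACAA) stood at -2.67 ± 0.86 with an adjusted p of 1.05e-05. Of the probes called at 3 h, 1002 were called higher and 240 called lower at 6 h too, and 0 went the opposite way; the processed signals gave 1320 and 519. Independent lists of these lengths would share 43.3 increases and 5.24 decreases. Same-numbered arrays of both times carry the same, or nearly the same, 0 h RNA. In simulated unchanged tissue, with the deviations of same-numbered arrays turned together in 14 sign patterns, a mean of 12.2 probes were shared in each direction, with up to 135 in a single pattern. The covariance of the log2 ratios across probes was 0.232, against 0.0176 in the simulations. The simulations hold no constant dye effect of a probe, which could give shared calls, covariance and correlation in unchanged tissue. They therefore cannot part a response from dye. With 3 h values from 2 replicates and 6 h values from the remaining 2, so that no array number was shared, the correlation across probes was 0.69 to 0.81; probes are not independent replicates.

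More probes were called in root than in shoot, and in both directions. At 3 h in root, 2676 probes were called higher and 2102 lower, 12.1% of all probes tested against 4.24% in shoot. The processed signals gave 3322 higher and 3292 lower, so the excess of increases depends on the scaling. Hv2095B22_2 (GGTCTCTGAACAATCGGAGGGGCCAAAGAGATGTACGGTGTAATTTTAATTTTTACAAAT) had the highest mean log2 ratio, 6.88 ± 0.85 (SD, n = 4), a 118-fold increase with an adjusted p of 2.36e-09. Hv2120G13_1 (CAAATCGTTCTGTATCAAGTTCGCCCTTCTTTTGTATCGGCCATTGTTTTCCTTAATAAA) had a mean of 6.57 ± 0.74. Both probes also rose in shoot at 3 h, by means of 4.62 ± 0.90 and 5.10 ± 1.17. The sequence of Hv2095B22_2 shares a stretch of 14 bases, CCAAAGAGATGTAC, with that of Hv2083E12_1, the probe highest in shoot at 6 h. Among decreases, Hv2009P09_1 (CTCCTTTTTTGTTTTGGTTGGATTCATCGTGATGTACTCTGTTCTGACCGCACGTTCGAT) had the lowest mean, -3.98 ± 0.91, with an adjusted p of 2.7e-07, and Hv2019J20_1 stood at -3.84 ± 0.68. Decreases of at least 4-fold numbered 287 and increases of at least 4-fold 619. The dimmer channel was never well above background for 8 called increases and 6 called decreases, whose folds are bounds.

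After 6 h the root had 2094 probes called higher and 2165 called lower. Which direction was more frequent depends on the setting, since median centring gave 2766 higher and 2158 lower and the fit without replicate 3 gave 2103 and 2042. Hv2095B22_2 remained the highest at a mean log2 ratio of 6.03 ± 0.30 (SD, n = 4) and Hv2120G13_1 the next at 5.87 ± 0.32, increases of 65.2-fold and 58.7-fold. Hv1009G20_1 (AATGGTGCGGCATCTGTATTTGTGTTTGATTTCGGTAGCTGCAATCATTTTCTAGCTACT) had the lowest mean, -4.20 ± 0.48, an 18.4-fold decrease with an adjusted p of 8.26e-07. Hv3093P03_1 followed at -3.89 ± 0.69, with an adjusted p of 0.00011. In shoot at 6 h these last 2 probes stood at -0.92 ± 0.27 and -0.54 ± 1.75, and neither was called. From 3 h to 6 h, 1779 increases and 1646 decreases were called at both times, and 0 probes were called in opposite directions. The processed signals gave 2323 shared increases and 2526 shared decreases, and the fit without replicate 4 gave 1576 and 1665. Independent lists would share 142 and 115. Simulated unchanged roots shared a mean of 27.0 in each direction, with up to 204 in a single pattern. The covariance across probes was 0.456, against 0.0301 in the simulations, and the correlation across probes between separate replicates was 0.72 to 0.87. A constant dye effect, absent from the simulations, could raise shared calls, covariance and correlation here too.

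**Figure D2:**
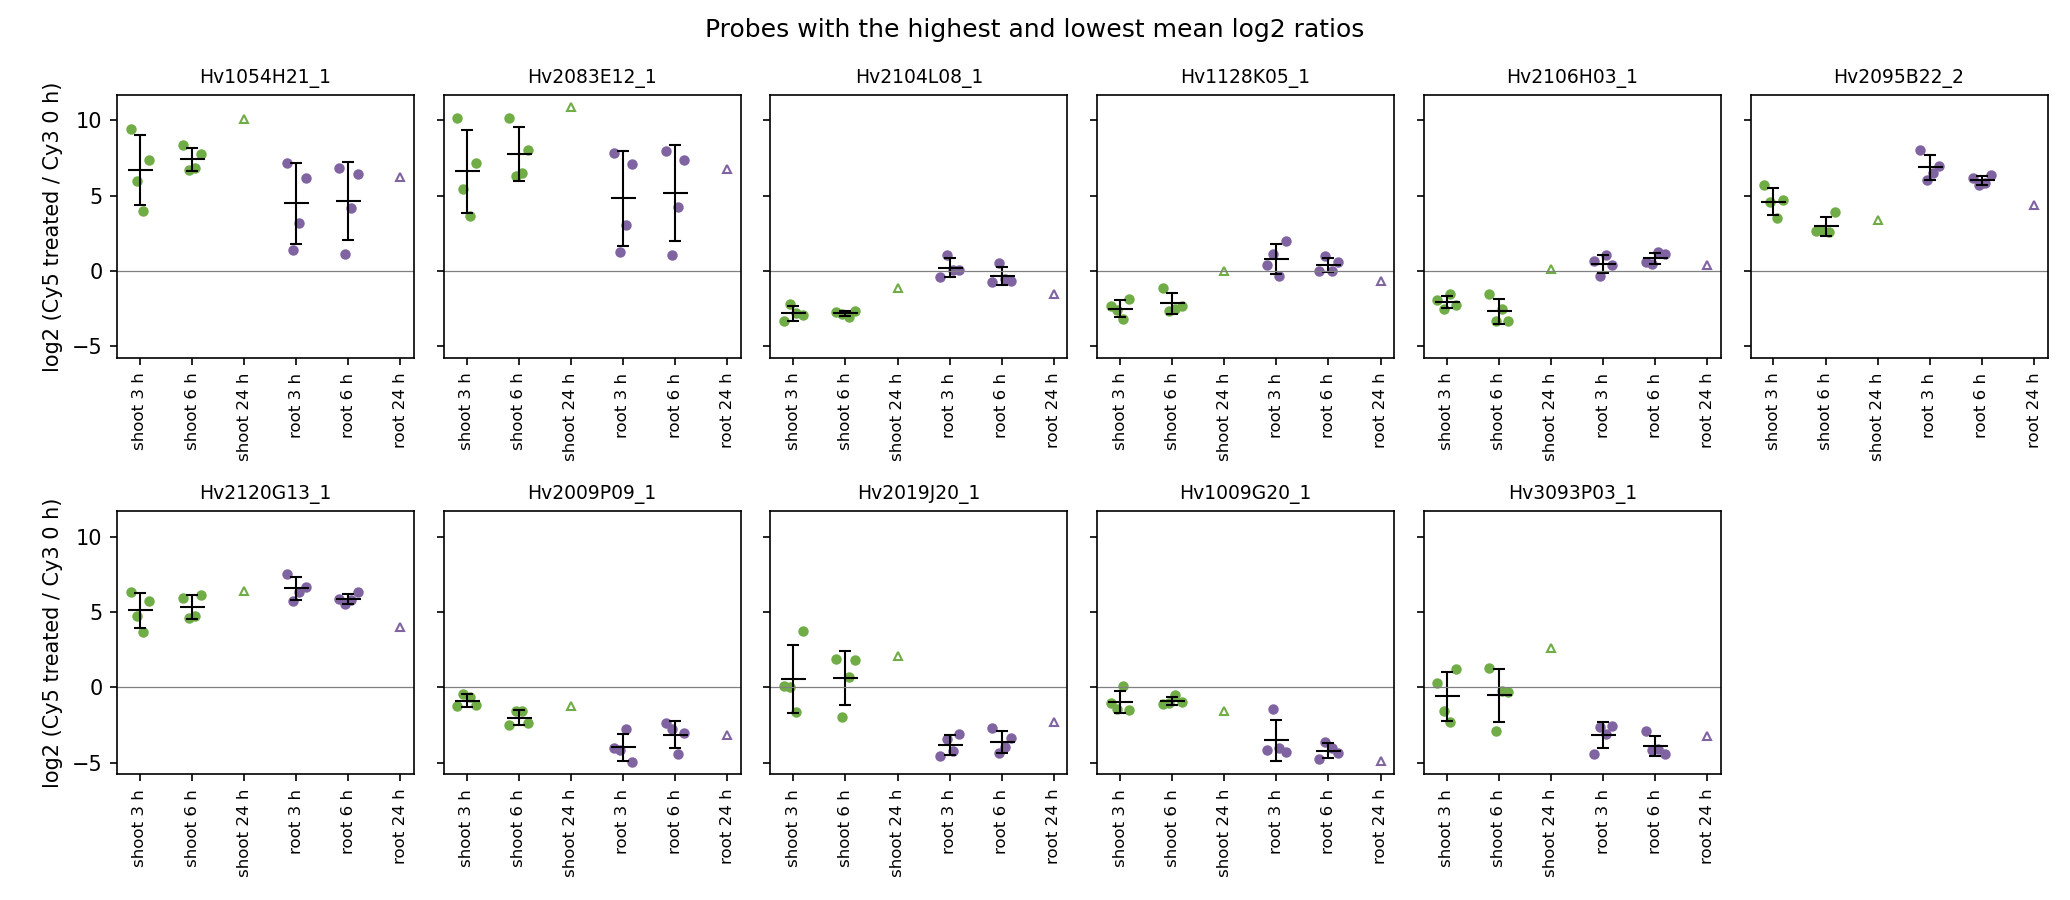
Log2 ratio of treated (Cy5) over 0 h (Cy3) RNA for the 11 probes with the highest or lowest means in a tissue and time, one panel per probe. Filled points are the 4 replicate arrays of a group, bars are their mean and SD, and open triangles are the single 24 h arrays; Hv1054H21_1 and Hv2083E12_1 spread widely between replicates in root, whereas Hv2095B22_2 and Hv2120G13_1 lay above 5 on every root array at 3 h and 6 h.

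The difference between 6 h and 3 h was tested directly in each organ, where a dye effect cancels. In root, 41 probes were called, 10 with a higher and 31 with a lower ratio at 6 h. Hv2011N24_2 (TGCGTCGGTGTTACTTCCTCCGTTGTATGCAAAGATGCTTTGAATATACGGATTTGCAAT) had a mean log2 ratio of 3.65 ± 0.76 at 3 h and 1.42 ± 0.36 at 6 h (SD, n = 4), a difference of -2.22 with an adjusted p of 0.0153. Hv1125H15_1, whose probe shares 33 bases with it, went from 3.48 ± 0.80 to 1.39 ± 0.37. In the other direction, Hv2029E11_1 went from -1.27 ± 0.57 to 0.05 ± 0.17, and Hv2093P23_1 from -0.89 ± 0.35 to 0.36 ± 0.34. The count in root fell when any replicate was left out of all 4 groups. It was 14 without replicate 1, 1 without replicate 2, 6 without replicate 3 and 6 without replicate 4. Each of the 4 probes just named lost its call in at least 1 of those fits. Fewer arrays then estimate the spread, so the lower counts do not show dependence on single root arrays. Same-numbered arrays deviated together, and with the replicate number as a block the root count was 92, or 208 with a block within each tissue. The scanner software's processed signals gave 14, of which 5 were higher at 6 h. In shoot, limma called 0 probes, with 3465 at an unadjusted p under 0.05, 77 of these at least 2-fold, and a lowest adjusted p of 0.0722. The replicate block left the shoot count at 0, and a block within each tissue raised it to 68, with 15 higher and 53 lower at 6 h.

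Whether shoot and root responded differently was tested as the difference of their log2 ratios. This removes a constant dye effect where a probe is bright in both organs. At 3 h, 3891 probes were called, 2216 with the higher ratio in shoot and 1675 with the higher ratio in root. Hv2098D06_1 (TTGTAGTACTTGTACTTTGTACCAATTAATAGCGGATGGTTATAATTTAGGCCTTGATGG) had a mean of 3.93 ± 0.76 in shoot and -2.0 ± 1.02 in root (SD, n = 4), a difference of 5.93 with an adjusted p of 1.74e-05. Hv2141G06_1 likewise stood at 3.33 ± 0.57 in shoot and -1.90 ± 0.96 in root. Hv2033D08_1 (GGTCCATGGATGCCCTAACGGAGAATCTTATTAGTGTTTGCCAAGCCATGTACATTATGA) had 5.50 ± 1.00 in root and -0.24 ± 0.59 in shoot, and Hv2115D22_1 had 5.66 ± 0.60 in root and 0.31 ± 1.02 in shoot. At 6 h, 3352 probes were called, 2021 with the higher ratio in shoot and 1331 with the higher ratio in root. Hv3116L10_1 stood at 0.76 ± 0.13 in shoot and -3.61 ± 0.25 in root, a difference of 4.37 with an adjusted p of 5.39e-08. Hv2017D02_2 had 4.60 ± 0.89 in shoot, whereas in root its Cy5 signal was not well above background on any array, so its difference of 4.66 has no measured root ratio behind it. Hv2033D08_1 kept a difference of -4.91 at 6 h, and Hv2044A19_1 stood at 4.13 ± 1.71 in root and 0.24 ± 0.09 in shoot, where it was well above background in Cy5 on 2 arrays. Without replicate 2 the difference of Hv2033D08_1 was -6.36 at 3 h and -5.58 at 6 h, and that of Hv2044A19_1 was -4.69.

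Part of the called probes were called in both organs. At 3 h, 704 probes were called higher and 85 lower in both organs, while 32 were called in opposite directions; independent lists would share 92.7 and 16.4. Simulated unchanged tissue shared a mean of 10.3 in each direction, but up to 109 in a single pattern, more than the 85 shared decreases. The simulated deviations also hold replicate differences in response size, so this cannot decide whether these 85 stand apart from unchanged tissue. The scanner software's processed signals gave 885 higher and 257 lower in both. At 6 h, 593 were called higher and 199 lower in both, with 30 in opposite directions, against 66.4 and 37.0 for independent lists and up to 77 in a simulated pattern. The processed signals gave 1230 shared probes at 6 h, 802 higher and 428 lower. Without replicate 1 the shared decreases numbered 53 at 3 h and 113 at 6 h. The covariance of shoot and root log2 ratios was 0.165 at 3 h and 0.166 at 6 h, against 0.0108 and 0.00792 in the simulations. As within an organ, the simulations hold no constant dye effect, which both organs could share. Called higher at both times in both organs were 474 probes from 378 clones, and called lower throughout were 64 probes from 55 clones. Hv2120G13_1 was among the former, with means between 5.10 and 6.57. Hv2095B22_2 was as well, and its lowest mean was 2.97 ± 0.64 in shoot at 6 h (SD, n = 4).

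The 24 h arrays are of replicate 1 alone and allow no test. In shoot, 3297 probes were at least 2-fold higher and 3237 at least 2-fold lower than at 0 h, compared with 2145 and 1769 on the 6 h array and 2217 and 1121 on the 3 h array of that replicate. In root, 2252 were at least 2-fold higher and 3641 lower, compared with 2795 and 3032 at 6 h and 3672 and 3417 at 3 h. With median centring in place of loess the 24 h counts were 2788 and 3189 in root and 3710 and 2831 in shoot. The processed signals gave 3657 and 4610 in root and 4336 and 4526 in shoot, so the balance in shoot depends on the scaling. The 24 h arrays share slide 1 with the 3 h arrays of replicate 1, while its 6 h arrays are on slide 2, read on another scanner with another software release, so a change from 6 h to 24 h is also one between slides. Probes called at 6 h from the other replicates were then followed through replicate 1. Not every called probe was followed: in shoot at 3 h the sets held 1073 higher and 224 lower, against 1325 called without replicate 1. In shoot, the 1011 probes called higher had a median log2 ratio of 1.85 at 6 h and 1.67 at 24 h, and 77.9% were at least 2-fold up at 24 h, against 92.6% at 6 h. In root, the 1865 probes called higher had medians of 1.64 at 6 h and 0.96 at 24 h, and 47.3% were at least 2-fold up at 24 h, against 82.7% at 6 h. The 1987 probes called lower in root kept a median of -1.30 at 24 h, against -1.43 at 6 h, and the 454 called lower in shoot one of -1.48, against -1.45. The 224 probes called lower in shoot at 3 h went the other way, with medians of -1.24 at 6 h and -0.92 at 24 h. Among 10000 random lists matched for size and intensity, the 24 h medians of the sets called higher lay at percentile 100 and those of the sets called lower at percentile 0, as a description of these arrays. Hv1054H21_1 stood at 10.10 in shoot at 24 h, against 9.45 at 3 h and 8.33 at 6 h in the same replicate. Hv2083E12_1 stood at 10.89, against 10.17 at 3 h and 10.18 at 6 h in that replicate. Hv2095B22_2 stood at 4.42 in root at 24 h and Hv1009G20_1 at -4.87, against 6.19 and -4.78 at 6 h in replicate 1. Hv1128K05_1 and Hv2106H03_1, both called lower in shoot at 3 h and 6 h, stood at 0.02 and 0.14 in shoot at 24 h. In replicate 1 they had stood at -2.32 and -1.92 at 3 h and at -1.10 and -1.53 at 6 h.

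**Figure D3:**
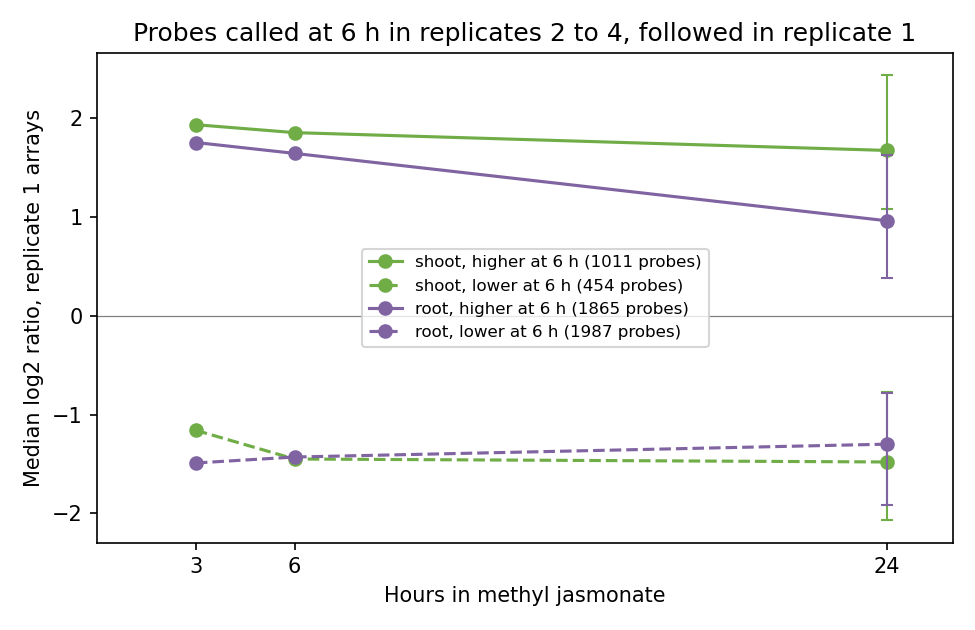
Median log2 ratio on the replicate 1 arrays (vertical axis) against hours in methyl jasmonate (horizontal axis) for probes called at 6 h from replicates 2 to 4; solid lines are probes called higher, dashed lines probes called lower, and bars at 24 h span the interquartile range. The root set called higher had medians of 1.64 at 6 h and 0.96 at 24 h; the shoot set had 1.85 and 1.67.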

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

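Among the tests in this part, the one on probes whose response differed between organs was chosen after its result was seen. Of the 40 group-wise array measures and 40 group-wise probe values examined for a replicate far from the others, 9 and 2 stood apart; chance gives about 1 in 20.

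Arrays that stood apart were these. Spots marked as outliers by the scanner software numbered 394 on shoot 6 h replicate 1 and 497 on root 6 h replicate 1, against at most 6 and 12 on the other arrays of these groups. The median Cy5 signal of root 6 h replicate 1 was 2298, against 1796 to 1855, and its Cy5 background 62, against 55 to 56. The Cy3 background of replicate 4 was 67 in shoot at 6 h, against 48 to 51, and 68.5 in root at 6 h, against 49.5 to 52. On shoot 6 h replicate 4, 90.7% of the probes were well above background in Cy5, against 88.4% to 88.7%. The slope of observed on expected spike-in ratios was 0.748 on shoot 3 h replicate 1, against 0.867 to 0.875, and 0.742 on root 3 h replicate 1, against 0.858 to 0.875. Spike-ins are not used in the comparisons. On slide 1, which holds both of these arrays, the spike-in r60_a135 had a mean log2 ratio of 2.23. On the other arrays it ranged from -2.22 to -0.08. Slide 1 was the only slide read on its scanner. The intercept of observed on expected spike-in log2 ratios was 2.20 to 2.37 there, against -1.04 to 0.997 elsewhere. Relative to the mean of an array's spike-ins, r60_a135 was 1.51 higher on slide 1, and the next largest gap of a spike-in was 1.28. Further checks of the spike-ins, of the pairing and of probes alike in sequence were written as tests of explanations and, once their results had been seen, kept as values only. A different slope set an array's spike-in ratios against their means over the arrays off slide 1. With all spike-ins it was 0.838 to 0.852 on slide 1. Without r60_a135, picked for the largest gap in these data, it averaged 0.923 there, within the 0.892 to 1.04 of other arrays. Slopes were also taken of an array's log2 ratios on the mean of the remaining replicates of its group, over probes called without replicate 1. They were the highest of the 4 replicates on both 3 h arrays of slide 1, at 1.23 in shoot and 1.11 in root. Replicate 4, which is not on slide 1, followed at 1.16 and 1.08. Deviations of same-numbered arrays correlated at a mean of 0.543 in Cy5, the treated channel, as well as 0.908 in Cy3. The log2 ratio of Hv2011N24_2 on root 3 h replicate 1 was 2.52, against 3.87 to 4.10, and that of Hv1125H15_1, which overlaps it in sequence, was 2.28, against 3.76 to 3.95.

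The response differed between organs for 3891 probes at 3 h and 3352 at 6 h. Of 35 splits of the arrays into 4 against 4, 1 gave as many calls in each case, the real one. The highest other counts were 2 and 3, from splits that mix both organs in each group, which widens their spread. A share of 1 in 35 treats the arrays as unpaired, so it does not exclude chance for paired samples. Since the numbers pair the samples, the real split was also set against the 8 splits that part all 4 pairs, which are too few for a share under 0.05; the highest other counts among these were 0 and 3. The named differences of shoot minus root were 5.93 for Hv2098D06_1, 5.23 for Hv2141G06_1, -5.74 for Hv2033D08_1 and -5.35 for Hv2115D22_1 at 3 h, and 4.66 for Hv2017D02_2, which has no measured root ratio since its Cy5 signal was not well above background on any root array at 6 h, 4.37 for Hv3116L10_1, -4.91 for Hv2033D08_1 and -3.89 for Hv2044A19_1 at 6 h. Untreated shoot and root differed at 15540 probes, and 1 of 35 splits reached this, the real one, with 34 as the highest other count, or 0 among those that part all 4 pairs. For treated tissue against 0 h, the 8 sign patterns of 4 arrays are too few for a share under 0.05: 1 of 8 gave as many calls, the real one, with 1672, 1922, 4778 and 4259 calls against highest other counts of 0, 7, 0 and 37 in shoot at 3 h, shoot at 6 h, root at 3 h and root at 6 h.

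In root, 41 probes differed between 6 h and 3 h, with differences of 1.32 for Hv2029E11_1, 1.25 for Hv2093P23_1, -2.22 for Hv2011N24_2 and -2.09 for Hv1125H15_1. Chance is not excluded over all splits, since 3 of 35 gave as many calls. The largest, with 1334, set replicates 1 and 4 against replicates 2 and 3, and the next, with 82, set replicates 1 and 3 against 2 and 4, so these splits follow the replicate numbers and show a structure of the samples. The real split was compared also with the 8 splits that part all 4 pairs, which are too few for a share under 0.05; the highest of the others called 0. In shoot, all 35 splits gave at least the real count of 0, and the largest, with 164, again set replicates 1 and 4 against 2 and 3. With the replicate block the counts were 92 in root and 0 in shoot, with the number as a random block 78 and 7, and with a block within each tissue, chosen after seeing the data, 208 and 68, so the count in shoot depends on how the pairing is fitted.

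Probes called in the same direction at both times and in both organs numbered 538, and without a dye swap a constant dye effect of the probe could give such a pattern. A constant dye effect would give equal ratios in all 4 groups for probes bright in both organs. Where a probe is near background in 1 organ, the offset of 50 draws its ratio there towards 0. Of the 538 probes, 23.6% had 4 group means within 0.5 of each other, between the shares of 50 and 10 percent fixed as bounds. For 119 of the 538 the difference between organs was itself called. This argues against dye as the whole cause for those of the 119 that are bright in both organs. For the rest it stays open. A response to methyl jasmonate and one to the transfer or the hours since 0 h cannot be told apart for any of the 538, as no mock-treated seedlings are on the arrays.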

How the results depend on the processing

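Slide-based fits, the block within each tissue, 1 probe per clone and the fit without slide 1 were chosen after seeing the data. Of 622 values of named probes under alternatives, 0 reversed and 31 lost their call, 30 of them for the 4 probes named for 6 h against 3 h in root. Counts of called probes stayed within 1.5 times in 217 of 262 cases. Some of these alternatives could not change a result, so both tallies overstate the stability. Aquantile normalisation after loess left the ratios unchanged, and dropping the fold minimum could not end a call. The processed signals and the value table hold the same ratios but were counted separately. The processed signals of the scanner software, and the series' value table, which holds the same ratios, called 2551 probes in shoot at 3 h, 2942 in shoot at 6 h and 14 for 6 h against 3 h in root; the cause was not tested. They also called 1230 probes in both organs at 6 h, against 792. With no minimum fold the counts were 13688 and 14540 in shoot at 3 h and 6 h, 21699 and 20163 in root, 176 for 6 h against 3 h in root, 14012 and 12542 between organs and 28229 between untreated organs. Tested against a 2-fold change with treat, they were 255, 250, 1397, 1045, 0, 397, 295 and 10161 in that order; the former follows from dropping the fold minimum and the latter from testing against a 2-fold change in place of 0. For 6 h against 3 h, root gave 0 fitted alone, where fewer arrays estimate the spread, 92 with the replicate block, 78 with the number as a random block, 208 with a block within each tissue, 27 without the slide 1 arrays, and 1 to 14 without each replicate, where fewer arrays remain. Shoot gave 7 with the random block, 3 on Cy5 intensity alone, 68 with the block within each tissue, and 0 to 1 without each replicate; the cause of the others was not tested. The replicate block, which pairs the arrays, changed no other count by over 1.5 times and ended no call of a named probe. The series' value table and processed ratios give no untreated comparison. The alternatives for gene lists (estimated correlation, fry, all probes) were not run. Signal near background leaves a bound for 8 increases and 6 decreases in root at 3 h, 5 and 13 at 6 h, and 5 and 2 increases in shoot.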

Other observations

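Of the tests in this part, those on the gain of root-rich transcripts and on a change in the root were chosen after the pattern was seen. Probes rich in one organ were selected on the untreated channels of replicates 1 and 2 (a difference of at least 3 in log2 between organs) and their responses were read on replicates 3 and 4, so that selection and ratio did not share 0 h RNA.

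Treated shoots showed increases among transcripts that untreated seedlings held mainly in the root. On the 4 held-out shoot arrays, 8.76%, 24.7%, 15.6% and 19.7% of the 1415 root-rich probes were at least 2-fold up. Of probes matched for shoot intensity with little difference between organs, 0.99%, 3.11%, 1.20% and 3.04% were, so the share was higher on 4 of 4 arrays. These arrays are 3 h and 6 h of replicates 3 and 4, and same-numbered arrays deviate together, so they are not 4 independent samples. The median of the root-rich probes stayed between 0.01 and 0.21, so most did not move by much. Root-rich probes were also at least 2-fold down more often than matched probes on these arrays, at 8.90%, 2.19%, 2.90% and 4.81% against 0.636%, 0.424%, 1.41% and 0.353%, so the set varied more in both directions, and on replicate 3 at 3 h decreases were as frequent as increases. A hypothesis is that part of the root-rich set may be inducible in the shoot, but a larger spread of these probes would also raise the share going up, and the test does not part them. Root tissue mixed into the treated shoot samples was predicted to raise the most abundant root transcripts most, though a ratio also depends on a probe's level in shoot. The median log2 ratio of the 50 root-rich probes brightest in root was at most 0.404. At 3 h and 6 h it was -0.177 and -0.104 on replicate 3, which argues against admixture as the cause there. On replicate 4 it was 0.184 and 0.404, against 0.214 and 0.204 for all root-rich probes. There 17 and 12 of the 50 lay below 0, so some admixture in replicate 4 stays open. A response to the transfer stays open. On the single 24 h shoot array, whose replicate helped select the set, 32.4% of the root-rich probes were at least 2-fold up.

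In roots, most of the 50 shoot-rich probes brightest in shoot had ratios below 0. These 50 probes had median log2 ratios of -2.23 and -0.475 on the held-out root arrays at 3 h and -2.11 and -1.47 at 6 h, whereas all 3011 shoot-rich probes had medians of -0.23, -0.08, -0.21 and -0.13, and 40 to 46 of the 50 were below 0 on each array. Between 46 and 48 of them were well above background in the untreated root channel. One candidate explanation is shoot tissue in the untreated root samples, which would lower all these probes by 1 factor; the interquartile range of their ratios was 0.903 to 1.98, above the 0.5 that this would allow, but on 1 array below the bound of 1 fixed for excluding it, so it stays open. A change in the root itself during the treatment cannot be told apart from one due to time, since the highest of the 4 medians, -0.475, has no mock-treated root beside it. On the single 24 h root array, whose replicate helped select the set, the median was -1.21.

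The intercept of observed on expected spike-in log2 ratios ranged from -1.04 to 2.37 over the 18 arrays. The 1857 pairs of probes from different clones that align over at least 40 bases with at least 80% identity had log2 ratios that correlated at 0.93 to 0.95 across pairs, against -0.013 to 0.00432 for random pairs, and at most 1 pair per group was called in opposite directions.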
